A study of Cricetulus griseus with 24 samples.

How the data were processed

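RNA was measured in 24 libraries of LR73 phagocytes in 2 experiments, as described in the results. Per the labels, Jurkat cells were made apoptotic with ultraviolet C light at 1500 mJ and kept for 4 h, co-culture in the second experiment lasted 2 h, and 75 bp paired-end reads were taken from libraries of total RNA. The co-culture time of the first experiment and the way Slc12a2 was removed are not given in the sources used here. The cells are named fibroblasts in the labels.

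The values used are raw fragment counts per gene name, made by the authors with featureCounts 1.5.0 from STAR alignments, per the file headers. Fragments with both ends aligned were counted over exons, with no strand option, per the file headers. FastQC, STAR, featureCounts and DESeq2 are named without versions in the submitters' processing notes. The STAR version and the genome build are not given in the sources used here, and the build of the reference table, which served for names and gene order, may differ from it. Both count tables hold the same 26776 gene names, of which 11415 are identifiers without a symbol, and 22328 were matched to the reference by symbol, synonym or gene identifier. A row with a blank name was left out. It held a mean of 0.0361% of counts in control libraries and 1.34% in wildtype libraries of the second experiment. Wnk1 was not analysed here. Some items are not reported here. Counting intervals and floors cover counting error only.

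Each experiment was fitted by itself with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood F test on group alone. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The fit of the first experiment used all 16 libraries, and gave 4 contrasts, including the difference between the effects of apoptotic cells with and without cytochalasin D. Biological coefficients of variation were 7.04% and 6.06%. CPM levels of genes are TMM-scaled, and shares in ppm use raw counts. The floor of 3 counts corresponded to 0.105 to 0.363 CPM per library, and no fold is given against a group without a count. Counting intervals are at 95%. For 4 libraries against 4, exact permutation tests are two-sided over 70 assignments.

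These choices, 24 gene lists and the rule for named genes were fixed before the data were examined. The lists cover chloride sensing, glycolysis and its transporters, inflammation, restraint of inflammation, apoptotic cell uptake, cholesterol synthesis, LXR and cholesterol efflux, MRTF and serum response factor targets, immediate early genes, YAP targets, TGF-beta and BMP targets, oxidative stress and Nrf2, the unfolded protein and integrated stress responses, heat shock, interferon, cell cycle, p53, hypoxia, lysosome, extracellular matrix, T cells, myeloid cells, mitochondrial RNA and solute carriers. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside an estimated correlation and fry. The mitochondrial list had 1 measured gene and no such test, so camera p values are adjusted over 23 lists per comparison. The rule took, per comparison, up to 10 genes per direction with the largest changes among called genes with a symbol, a mean of at least 4 CPM and groups that do not overlap. It added up to 4 members per list and direction (6 for solute carriers) and 6 genes in every comparison, Slc12a2, Wnk1, Oxsr1, Stk39, Slc2a1 and Slc16a1. The text names a subset of these genes, picked after their values were seen. Cebpd and Nr4a3 for the difference between effects, and Il11 under cytochalasin D, were dropped after their calls were seen to be lost without single libraries.

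Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, relative log expression factors, no filter, a filter of 1 CPM in 4 libraries, an adjusted p under 0.01, a minimum fold of 1.5, a robust fit, each library left out, a block on replicate or library number and a fit on the 8 compared libraries. Alternatives chosen after seeing the data were removal of 3 libraries that stood apart on the third principal component, removal of 117 genes under 0.5 CPM in control and cytochalasin D libraries, removal of each library's trend with gene length, and each library left out of the overlaps, correlations, target level and T cell share. The tests were run on simulated counts with 200 changed genes. For apoptotic cells against control, with 12946 genes, edgeR recovered 73.1%, 77.6% and 98.5% of genes changed 1.5-, 2- and 4-fold, with 7 false calls among 173. For the difference between effects, with 12960 genes, it recovered 53.7%, 79.1% and 89.4%, with 4 false calls, and for genotype, with 12957 genes, 79.1%, 92.5% and 100%, with 5. A simulated length trend in the first of these comparisons gave 510 false calls among 13106 genes, and 12 once the trend was removed.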

Results

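RNA-seq fragment counts were obtained from 24 libraries of LR73 cells, a hamster fibroblast-like line that takes up apoptotic cells. The apoptotic targets were Jurkat cells, a human T lymphocyte line. In the first experiment, 16 libraries fell into 4 groups of 4, namely phagocytes alone (control), phagocytes with cytochalasin D, phagocytes with apoptotic cells, and phagocytes with both. Cytochalasin D stops actin filaments from growing and thereby blocks engulfment. In the second experiment, wildtype and Slc12a2-deficient phagocytes were co-cultured with apoptotic cells for 2 h, and cells carrying the acid-activated dye CypHer5E, a mark of engulfed targets, were sorted, giving 4 libraries per genotype. Slc12a2 encodes the sodium, potassium and chloride cotransporter NKCC1. Counted fragments per library ranged from 8275769 to 18917152 in the first experiment and from 23059998 to 28838553 in the second. Levels are given as mean CPM (counts scaled to library size) ± SD over 4 libraries per group, and fold changes come from edgeR.

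Slc12a2 itself was measured first, in every library of the second experiment. Its level was 93.43, 91.25, 99.51 and 103 CPM in the wildtype libraries and 25.35, 22.45, 24.72 and 26.15 CPM in the Slc12a2-deficient libraries. The deficient mean of 24.7 ± 1.59 CPM was 25.5% of the wildtype mean of 96.8 ± 5.41 CPM (two-sided exact permutation test, p = 0.0286, the smallest that 70 assignments allow). The log2 fold change was -1.97 (SE 0.06, edgeR adjusted p = 1.15e-12), so each library carried the Slc12a2 level its label calls for, and transcript was still present in the deficient cells.

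The comparison of phagocytes with and without apoptotic cells asks how contact with and uptake of corpses changes the phagocyte transcriptome. Inhibitors of DNA binding, which are targets of bone morphogenetic protein signalling, rose with apoptotic cells. Id1 rose 3.96-fold, from 8.48 ± 1.11 to 33.7 ± 5.38 CPM (log2 1.99, SE 0.16, edgeR adjusted p = 1.8e-08), Id3 rose 2.79-fold to 118 ± 18.9 CPM (edgeR adjusted p = 1.13e-06), and Id2 rose 1.72-fold (edgeR adjusted p = 2.6e-06). Smad6, an inhibitor in the same pathway, rose 3.06-fold from 2.82 ± 0.931 CPM (edgeR adjusted p = 0.000748), and Ltbp2, a matrix protein, rose 1.57-fold (edgeR adjusted p = 7.06e-07). Sgk1, a kinase regulated by serum, glucocorticoid and cell volume, rose 2.73-fold from 17.7 ± 2.11 to 48.4 ± 2.63 CPM (log2 1.45, SE 0.07, edgeR adjusted p = 5.76e-12). In the other direction, Trib3, a pseudokinase induced by amino acid and endoplasmic reticulum stress, was 2.08-fold lower, at 12.0 ± 0.758 against 25.1 ± 2.85 CPM (log2 -1.05, SE 0.11, edgeR adjusted p = 7.06e-07).

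Of 13106 genes tested, 1789 changed with apoptotic cells, 914 higher and 875 lower, most by small amounts, with a median absolute log2 change of 0.303. At least 2-fold changes were found for 168 higher and 18 lower genes, and 107 of the 168 (63.7%) were identifiers without a symbol, against 23.5% of the genes tested. Of the 168, 74 were near 0 without apoptotic cells and 94 were expressed without them. The CPM values of the groups did not overlap for 2566 genes (19.6%, where chance gives 2.86%). Among the other named genes, Cebpd (4.28-fold, edgeR adjusted p = 0.00163) and Nr4a3 (4.21-fold, edgeR adjusted p = 1.4e-06), both transcription factors, rose from 2.00 ± 0.986 and 1.59 ± 0.541 CPM. Slc14a1, a urea transporter, rose 2.42-fold (edgeR adjusted p = 1.8e-08), Ier5l 3.05-fold (edgeR adjusted p = 0.00312), Bola1 2.38-fold (edgeR adjusted p = 0.00346) and Arhgef17, a guanine nucleotide exchange factor, 2.65-fold (edgeR adjusted p = 7.37e-08). Amd1, an enzyme of polyamine synthesis, was 1.82-fold lower (edgeR adjusted p = 2.92e-08), and Ptprr (1.81-fold), Slc6a9, a glycine transporter (1.79-fold), Tp53inp1 (1.73-fold), Slc25a36 (1.73-fold) and Rapgef4 (1.61-fold) were also lower, with edgeR adjusted p from 1.57e-06 to 0.0107. Without apoptotic library 3 the count was 1103 (537 higher, 566 lower), without control library 1 the higher count was 606, and fold changes fell with gene length (Spearman correlation across genes -0.256, genes not being independent replicates).

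Gene lists showed which functions moved together with apoptotic cells. Of 29 immediate early genes measured, 13 rose and 1 fell (20 adjusted over the list alone). Dusp1 rose 1.51-fold and Ier3 1.74-fold (edgeR adjusted p = 2.33e-05 and 0.000357), and Klf6 was 1.21-fold lower (edgeR adjusted p = 0.00225). The list as a whole was higher than other genes (camera adjusted p = 4.21e-07, and adjusted p = 0.0793 with an estimated correlation). Of 14 TGF-beta and BMP targets, 6 rose and 1 fell (8 adjusted over the list alone; camera adjusted p = 0.00229, and adjusted p = 0.0564 with an estimated correlation). Of 36 cell cycle genes, 11 rose and none fell (12 adjusted over the list alone; camera adjusted p = 4.21e-07). Cdc20, Aurka and Rrm2 rose 1.28-, 1.32- and 1.22-fold (edgeR adjusted p from 1.38e-05 to 2.62e-05). Of 21 cholesterol synthesis genes, 9 fell and none rose (12 adjusted over the list alone; camera adjusted p = 4.21e-07). Hmgcs1, Insig1 and Msmo1 were lower by 1.34-, 1.43- and 1.37-fold (edgeR adjusted p from 5.07e-06 to 0.000537). Of 25 genes of the unfolded protein and integrated stress responses, 8 fell and 3 rose (14 adjusted over the list alone; camera adjusted p = 0.028, and adjusted p = 0.137 with an estimated correlation). Atf4, the transcription factor of the integrated stress response, was 1.46-fold lower at 195 ± 6.54 CPM (edgeR adjusted p = 1.69e-09), and Nupr1 was 1.38-fold lower (edgeR adjusted p = 4.58e-05). The cell cycle and cholesterol calls held with an estimated correlation (adjusted p = 0.000887 and 0.0202).

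Of 17 heat shock genes, 3 rose and none fell (5 adjusted over the list alone; camera adjusted p = 0.00287). Hspa8 stood at 2876 ± 40.5 against 2383 ± 114 CPM (1.21-fold, edgeR adjusted p = 1.15e-05), and this call held with an estimated correlation (adjusted p = 0.0215). Of 20 extracellular matrix genes, 5 rose (6 adjusted over the list alone; camera adjusted p = 0.0052, and adjusted p = 0.0564 with an estimated correlation). Of 18 genes that restrain inflammation, 6 rose and 2 fell (12 adjusted over the list alone), with the matrix protein Thbs1 up 1.27-fold (edgeR adjusted p = 5.24e-05; list camera adjusted p = 0.028, and adjusted p = 0.143 with an estimated correlation). Of 19 inflammatory genes, 3 rose and 4 fell (9 adjusted over the list alone; camera adjusted p = 0.453). Il11 rose 3.21-fold and Ptgs2 1.74-fold (edgeR adjusted p = 6.87e-05 and 0.000196), while Icam1 and Tlr2 were lower by 1.14- and 1.27-fold (edgeR adjusted p = 0.00939 and 0.00556). Of 23 genes of glycolysis and its transporters, 7 rose (7 adjusted over the list alone; camera adjusted p = 0.000147, and adjusted p = 0.137 with an estimated correlation). The median log2 change of this list was 0.0677 and the mean 0.553, so the mean rests on large rises of some members. The list result thus does not show a rise of glycolysis as a whole. Jurkat RNA as a source of those large rises was not tested for this list. The glucose transporter Slc2a1 stood at 103 ± 2.71 against 79.8 ± 3.27 CPM (1.29-fold, edgeR adjusted p = 0.000114) and Eno2 rose as well (1.58-fold, edgeR adjusted p = 0.000111). Of 176 solute carriers, 16 rose and 24 fell (52 adjusted over the list alone; camera adjusted p = 0.333). The amino acid transporter Slc7a1 was 1.45-fold lower (edgeR adjusted p = 0.000128).

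The chloride sensing list holds chloride cotransporters, WNK and SPAK kinases and volume-regulated channels. Of 21 measured, 3 fell with apoptotic cells and none rose (3 adjusted over the list alone), where 13.7% of all genes tested changed. The list was not shown to differ from other genes (camera adjusted p = 0.323), while fry, which tests for change in one direction against no change, gave adjusted p = 0.0131 for a decrease. Oxsr1, a kinase that WNK kinases activate, was 1.16-fold lower at 382 ± 6.36 CPM (log2 -0.21, SE 0.04, edgeR adjusted p = 0.00197). Slc12a2 (log2 -0.07, edgeR adjusted p = 0.686), Stk39, the kinase SPAK (log2 0.09, edgeR adjusted p = 0.223), and the lactate transporter Slc16a1 (log2 -0.01, edgeR adjusted p = 0.859) did not pass the test. Wnk1, set down for naming in advance, was not analysed here.

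Transcripts of T lymphocyte genes were also counted in these libraries. Of 13 T cell genes measured, 6 rose with apoptotic cells (8 adjusted over the list alone; camera adjusted p = 0.000147, and adjusted p = 0.00989 with an estimated correlation). The kinase Lck went from 0.0259 to 3.20 ± 0.277 CPM, a ratio with a 95% counting interval of 26.7 to 813, and Zap70 from 0.013 to 3.35 ± 1.41 CPM, with an interval of 37.2 to 8310. Lef1 had no count in the control and rose to 1.68 ± 0.36 CPM. The T cell list took 75.2 ± 4.37 ppm of counts with apoptotic cells and 65.3 ± 3.41 without (exact permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.0763 over 32 tests of library composition, with all 4 apoptotic libraries above all 4 controls). The exact p rose to 0.0571 without any one of control libraries 1 to 4 or apoptotic libraries 2 and 4, where the difference was between 8.38 and 11.4 ppm.

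**Figure D1:**
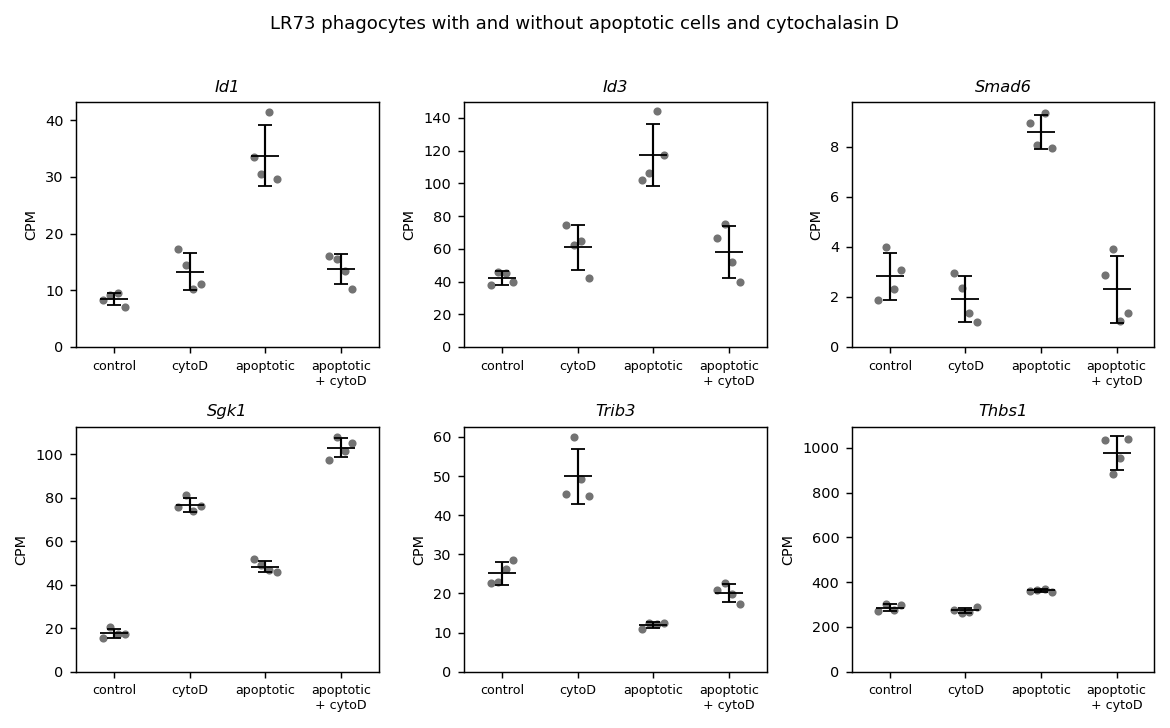
Expression in CPM (vertical axes) of Id1, Id3, Smad6, Sgk1, Trib3 and Thbs1 in the 4 groups of the first experiment (horizontal axes). Dots are single libraries and bars the mean ± SD of 4, showing Id1 at 33.7 CPM with apoptotic cells alone and 13.8 CPM with apoptotic cells and cytochalasin D, and Thbs1 at 363 and 978 CPM.

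Cytochalasin D was compared with control to measure what the actin inhibitor does without corpses. Genes driven by serum response factor and its actin-sensing cofactor MRTF rose almost throughout: 26 of 30 measured were higher and 1 lower (28 adjusted over the list alone; camera adjusted p = 2.94e-32, and adjusted p = 0.000196 with an estimated correlation). Myl9, a myosin light chain, rose 15.3-fold from 1.47 ± 0.496 to 21.6 ± 1.48 CPM (log2 3.94, SE 0.25, edgeR adjusted p = 1.88e-11), and smooth muscle actin Acta2 rose 14.8-fold from 1.01 ± 0.306 to 14.4 ± 1.24 CPM (log2 3.89, SE 0.21, edgeR adjusted p = 1.45e-12). The cytoplasmic actins Actg1 and Actb rose 9.8-fold and 3.15-fold, to 7789 ± 660.0 and 13736 ± 578 CPM (edgeR adjusted p = 8e-20 for each), and the 20 most abundant genes took 8.74% ± 0.174 of counts against 7.13% ± 0.169 in the control (exact permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.0763 over 32 tests). The adhesion protein Zyx rose 4.66-fold (edgeR adjusted p = 1.52e-17) and Pdlim5 4.99-fold (edgeR adjusted p = 7.65e-19).

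In all, 3451 genes changed with cytochalasin D, 1772 higher and 1679 lower, of which 169 and 72 by at least 2-fold. The receptor gene Gpr176 (5.58-fold), the stress factor Atf3 (5.61-fold), Sgk1 (4.33-fold) and the small GTPase Gem (3.67-fold) were among the genes with the largest rises, with edgeR adjusted p from 6.41e-18 to 7.64e-08. Egr1, an early growth response factor, was 5.91-fold lower, at 6.66 ± 0.969 against 39.3 ± 2.99 CPM (log2 -2.56, SE 0.11, edgeR adjusted p = 2.24e-14). The peptide hormone Apln (3.73-fold), Mid1 (3.18-fold), the uracil glycosylase Ung (2.97-fold), Gramd4 (2.57-fold) and the cytokine Il15 (2.56-fold) were lower as well, with edgeR adjusted p from 3.92e-15 to 8.43e-09. Immediate early genes went both ways, 16 of 29 higher and 3 lower (20 adjusted over the list alone; camera adjusted p = 8.73e-05, and adjusted p = 0.185 with an estimated correlation). Dusp1 rose 2.98-fold (edgeR adjusted p = 2.01e-13) and Klf4 was 1.87-fold lower (edgeR adjusted p = 1.71e-09).

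Lysosomal genes rose with cytochalasin D, 22 of 28 higher and 1 lower (25 adjusted over the list alone; camera adjusted p = 9.26e-17, and adjusted p = 0.000196 with an estimated correlation). The galactosidase Gla rose 3.37-fold to 71.3 ± 1.54 CPM (edgeR adjusted p = 2.01e-13), the autophagy receptor Sqstm1 2.65-fold to 175 ± 8.47 CPM (edgeR adjusted p = 2.1e-14), and the protease Ctsb 1.63-fold (edgeR adjusted p = 1.56e-13). Cell cycle genes fell, 19 of 36 lower and 2 higher (23 adjusted over the list alone; camera adjusted p = 3.38e-08, and adjusted p = 0.000196 with an estimated correlation). Ccne2, Cdc6, Rrm2 and Mcm6 were lower by 2.73-, 1.95-, 1.70- and 1.52-fold (edgeR adjusted p from 5.31e-13 to 5.12e-10). Of 17 p53 targets, 7 rose and none fell (7 adjusted over the list alone; camera adjusted p = 0.0014, and adjusted p = 0.0178 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose 1.74-fold to 262 ± 28.9 CPM (edgeR adjusted p = 7.41e-09) and the death receptor Fas rose 1.74-fold (edgeR adjusted p = 3.85e-09). Of 21 cholesterol synthesis genes, 11 fell (12 adjusted over the list alone; camera adjusted p = 1.46e-06, and adjusted p = 0.0178 with an estimated correlation). Insig1 was 1.61-fold and Hmgcs1 1.42-fold lower (edgeR adjusted p = 5.76e-08 and 4.73e-08).

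Targets of the coactivator YAP were mixed under cytochalasin D, 9 of 19 lower and 2 higher (11 adjusted over the list alone; camera adjusted p = 0.000288, and adjusted p = 0.104 with an estimated correlation). Ctgf was 3.20-fold lower at 6.37 ± 2.05 CPM (edgeR adjusted p = 3.03e-09), Ajuba 2.08-fold and Amotl2 1.81-fold lower (edgeR adjusted p = 7.32e-15 and 1.24e-10), while Cyr61 and Ankrd1 rose 2.59- and 2.48-fold (edgeR adjusted p = 6.5e-14 and 1.8e-05). Of 21 chloride sensing genes, 6 rose and 3 fell (9 adjusted over the list alone; camera adjusted p = 0.297). Slc12a2 was 1.60-fold lower at 31.0 ± 5.79 against 49.8 ± 3.69 CPM (log2 -0.68, SE 0.10, edgeR adjusted p = 1.53e-05), and Oxsr1 was 1.17-fold lower (edgeR adjusted p = 0.000324). The volume-regulated channel subunit Lrrc8a rose 1.38-fold (edgeR adjusted p = 0.000138), and Stk39 did not pass (log2 -0.05, edgeR adjusted p = 0.536). Of 176 solute carriers, 23 rose and 36 fell (63 adjusted over the list alone; camera adjusted p = 0.264). Slc2a1 rose 1.41-fold (edgeR adjusted p = 2.75e-07) and the creatine transporter Slc6a8 2.30-fold (edgeR adjusted p = 2.2e-13). Slc16a1 was 1.23-fold lower (edgeR adjusted p = 7.36e-06) and the taurine transporter Slc6a6 1.504-fold lower (edgeR adjusted p = 1.25e-11).

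**Figure D2:**
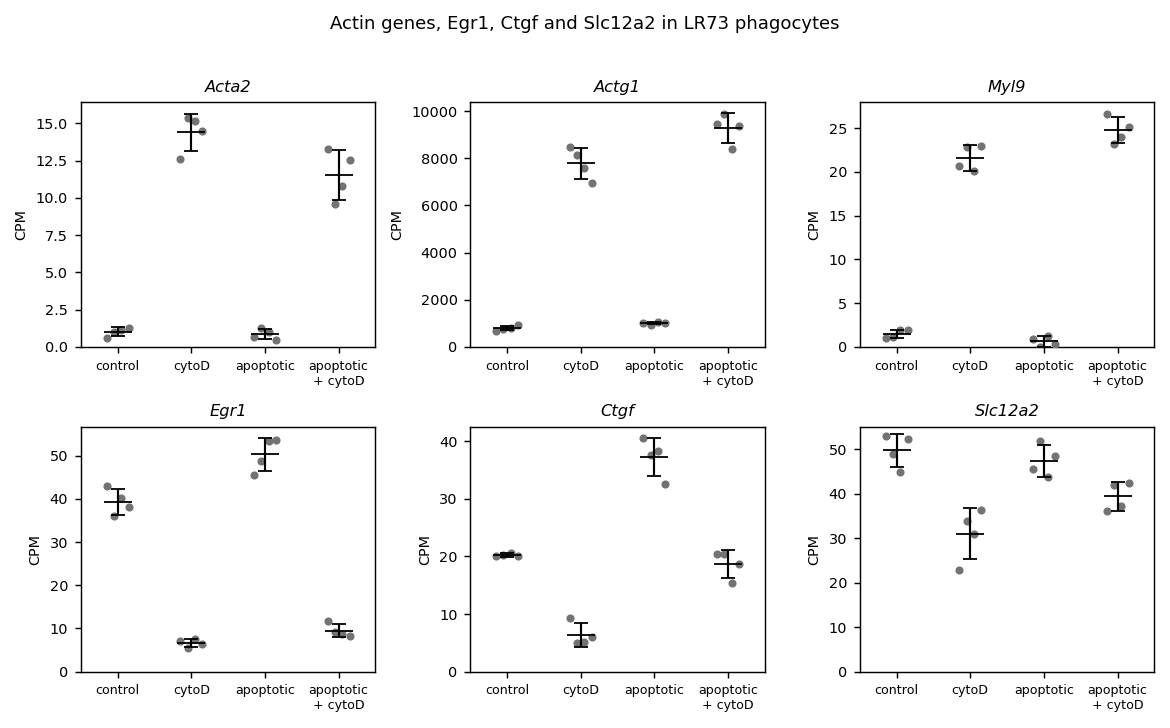
Expression in CPM (vertical axes) of Acta2, Actg1, Myl9, Egr1, Ctgf and Slc12a2 in the 4 groups of the first experiment (horizontal axes). Dots are single libraries and bars the mean ± SD of 4, and Acta2 lies at 1.01 CPM in the control and 14.4 CPM with cytochalasin D, Slc12a2 at 49.8 and 31.0 CPM.

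Apoptotic cells were then compared with their absence under cytochalasin D, where corpses can touch but are not expected to enter phagocytes. Thbs1 rose 3.58-fold, from 274 ± 12.4 to 978 ± 75.0 CPM (log2 1.84, SE 0.05, edgeR adjusted p = 1.43e-17), and the YAP targets Ankrd1, Ctgf and Cyr61 rose 3.38-, 2.95- and 2.25-fold (edgeR adjusted p = 1.18e-07, 1.33e-07 and 5.81e-12). The natriuretic peptide Nppb rose 2.62-fold from 10.8 ± 1.26 to 28.1 ± 1.86 CPM (log2 1.39, SE 0.12, edgeR adjusted p = 4.79e-08), Arhgef17 2.26-fold (edgeR adjusted p = 1.15e-06) and the metalloprotease Mmp10 2.19-fold (edgeR adjusted p = 0.00113). Trib3 was 2.48-fold lower, at 20.2 ± 2.26 against 49.9 ± 7.02 CPM (log2 -1.31, SE 0.10, edgeR adjusted p = 1.11e-08), the antiviral gene Oasl 2.27-fold lower (edgeR adjusted p = 1.86e-07), and the chemokines Cxcl1 and Cxcl3 1.89- and 1.74-fold lower (edgeR adjusted p = 0.000145 and 1.41e-05). Rapgef4 (2.01-fold), Gli1 (1.92-fold), Notch1 (1.91-fold) and Traf1 (1.79-fold) were lower too, with edgeR adjusted p from 1.63e-06 to 0.006. Nr4a3 (1.83-fold) and Glmn (1.77-fold) rose (edgeR adjusted p = 0.00955 and 6.8e-05).

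With cytochalasin D present, 1129 genes changed with apoptotic cells, 632 higher and 497 lower, of which 128 and 12 by at least 2-fold. Of 25 stress response genes, 7 fell and 1 rose (10 adjusted over the list alone; camera adjusted p = 8.07e-06, and adjusted p = 0.0108 with an estimated correlation). Atf4 was 1.505-fold lower (edgeR adjusted p = 2.41e-10) and Nupr1 1.65-fold lower (edgeR adjusted p = 1.02e-07). Of 28 lysosomal genes, 7 fell and none rose (10 adjusted over the list alone; camera adjusted p = 1.69e-05, and adjusted p = 0.0166 with an estimated correlation). Sqstm1 was 1.81-fold lower at 96.6 ± 1.63 CPM (edgeR adjusted p = 1.5e-09). Of 29 immediate early genes, 7 rose and 1 fell (11 adjusted over the list alone; camera adjusted p = 0.0434, and adjusted p = 0.414 with an estimated correlation). Of 19 YAP targets, 6 rose and 1 fell (8 adjusted over the list alone; camera adjusted p = 0.00717, and adjusted p = 0.175 with an estimated correlation). Of 23 glycolysis and transport genes, 8 rose (10 adjusted over the list alone; camera adjusted p = 8.07e-06, and adjusted p = 0.0916 with an estimated correlation). Here too the median log2 change of the list was small, 0.0555 against a mean of 0.565, so the same limits hold. Slc2a1 rose 1.36-fold to 153 ± 7.66 CPM, Hk2 1.29-fold and Sgk1 1.34-fold (edgeR adjusted p from 2.82e-06 to 9.85e-05). Of 17 interferon genes, 3 fell (3 adjusted over the list alone; camera adjusted p = 0.00116, and adjusted p = 0.0916 with an estimated correlation). Of 11 genes of LXR and cholesterol efflux, 3 fell (3 adjusted over the list alone; camera adjusted p = 0.00909, and adjusted p = 0.193 with an estimated correlation). The cholesterol exporter Abca1 was 1.39-fold lower (edgeR adjusted p = 8.51e-06). Among genes that restrain inflammation, Tnfaip3 rose 1.58-fold and Nfkbia was 1.29-fold lower (edgeR adjusted p = 1.19e-08 and 9.22e-06), with 5 of 18 higher and 5 lower (14 adjusted over the list alone; camera adjusted p = 0.801).

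Of 21 chloride sensing genes, 1 was higher and 1 lower with apoptotic cells under cytochalasin D, where 8.61% of all genes tested changed (3 adjusted over the list alone; camera adjusted p = 0.936). Slc12a2 was 1.26-fold higher, at 39.4 ± 3.22 against 31.0 ± 5.79 CPM (log2 0.33, SE 0.10, edgeR adjusted p = 0.045), with overlapping groups. That call was lost without cytochalasin D library 1, 2 or 3 (edgeR adjusted p = 0.144, 0.0526 and 0.093) or library 2, 3 or 4 with both treatments (edgeR adjusted p = 0.117, 0.0691 and 0.135). With all libraries it was also lost with limma-voom (adjusted p = 0.0639), and in an edgeR fit on the 8 compared libraries (adjusted p = 0.102). Slc16a1 was 1.14-fold higher (edgeR adjusted p = 0.0067), and Oxsr1 and Stk39 did not pass (log2 0.00 and 0.01, edgeR adjusted p = 0.97 and 0.966). T cell genes rose in this comparison as well, 6 of 13 (6 adjusted over the list alone; camera adjusted p = 5.49e-07, and adjusted p = 0.00164 with an estimated correlation). Lck and Zap70 had no count with cytochalasin D alone and stood at 3.07 ± 0.824 and 2.96 ± 1.44 CPM with apoptotic cells. The T cell list took 79.3 ± 3.44 against 63.6 ± 1.55 ppm (exact permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.0763 over 32 tests). Without cytochalasin D library 2, or library 3 or 4 with both treatments, the lower count was 325, 308 or 318, and the counts were 662 (385 higher, 277 lower) without 3 libraries that stood apart from their groups (control 4, cytochalasin D 1 and library 4 with both treatments), a choice made after seeing the data.

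The difference between these effects, apoptotic cells with cytochalasin D minus apoptotic cells without it, was tested directly. Of 14 TGF-beta and BMP targets, 4 had a negative and 1 a positive difference (10 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.105). The difference in log2 effect was -1.92 for Id1 (SE 0.22, edgeR adjusted p = 2.16e-05), -1.55 for Id3 (SE 0.22, edgeR adjusted p = 0.000273) and -0.81 for Id2 (SE 0.13, edgeR adjusted p = 0.000601), and under cytochalasin D their levels with and without apoptotic cells were 13.8 and 13.3, 58.3 and 60.9, and 17.4 and 17.8 CPM. Sgk1 also rose less in log2 under cytochalasin D (difference -1.02, SE 0.10, edgeR adjusted p = 1.26e-06), from a level already at 76.8 ± 3.23 CPM. In CPM its rise there, to 103, was 0.857 of the rise from 17.7 to 48.4 without cytochalasin D. Thbs1 (difference 1.497, SE 0.07, edgeR adjusted p = 1.69e-12), Ankrd1 (1.77, SE 0.27, edgeR adjusted p = 0.000511), Cyr61 (1.00, SE 0.09, edgeR adjusted p = 4.73e-07) and Nppb (1.00, SE 0.17, edgeR adjusted p = 0.00163) responded more under cytochalasin D. Of 21 cholesterol synthesis genes, 9 fell with apoptotic cells alone, while under cytochalasin D 4 rose and 1 fell (5 adjusted over the list alone; camera adjusted p = 0.267). The difference was positive for 9 of the 21 and negative for none (9 adjusted over the list alone; camera adjusted p = 2.51e-06, and adjusted p = 0.0373 with an estimated correlation). Idi1, Msmo1 and Hmgcs1 differed by 0.93, 0.77 and 0.53 in log2 (edgeR adjusted p from 0.000126 to 0.000399).

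Of 20 matrix genes, 5 rose and none fell with apoptotic cells alone, while under cytochalasin D 1 rose and 3 fell (5 adjusted over the list alone; camera adjusted p = 0.145). The difference was negative for 5 of the 20 and did not pass for the other 15 (7 adjusted over the list alone; camera adjusted p = 0.000474, and adjusted p = 0.0373 with an estimated correlation). The difference was -0.53 for Col6a1 and -0.49 for Col6a2 (edgeR adjusted p = 8.55e-06 and 0.000452). Negative differences were also found for Gli1 (-1.18), Egr3 (-1.09), the chemokine receptor Ccr7 (-1.08), the mTOR inhibitor Ddit4 (-1.08), Cxcl1 (-0.88) and Cxcl3 (-0.83), with edgeR adjusted p from 0.000452 to 0.0132. Without the 3 libraries that stood apart, Egr3 (-0.90, edgeR adjusted p = 0.0954) and Cxcl1 (-0.76, edgeR adjusted p = 0.0795) lost their calls. Positive differences were found for Ptprr (1.11), Vgll3 (1.00) and the growth factor Hbegf (0.98), with edgeR adjusted p from 3.43e-06 to 0.00656. Differences for Slc12a2 (0.40, edgeR adjusted p = 0.098), Slc16a1 (0.20, edgeR adjusted p = 0.055), Slc2a1 (0.08, edgeR adjusted p = 0.596) and Stk39 (-0.09, edgeR adjusted p = 0.498) did not pass. Slc12a2 passed without cytochalasin D library 4 (edgeR adjusted p = 0.0253), Slc16a1 without that library (0.0134), apoptotic library 4 (0.0309) or library 1 with both treatments (0.0465). With all libraries, Slc12a2 also passed without a filter on low counts (edgeR adjusted p = 0.0418), and Slc16a1 with DESeq2 (adjusted p = 0.019), relative log expression factors (0.0492), no filter (0.0489) and a robust fit (0.0448). A replicate block passed Slc12a2 and Slc16a1 as well. Oxsr1 passed narrowly (0.22, SE 0.06, edgeR adjusted p = 0.044) and lost the call without control library 1, 3 or 4 (0.0618, 0.0617, 0.0896), cytochalasin D library 1, 2 or 3 (0.0898, 0.0761, 0.0809), apoptotic library 1, 3 or 4 (0.0649, 0.0879, 0.0718) or library 3 or 4 with both treatments (0.0928, 0.0932). It also lost the call with the length trend removed (0.16, edgeR adjusted p = 0.0773). In all, 598 genes differed, 397 with a positive and 201 with a negative difference, 13 and 23 of them by at least 2-fold. This count moved with single libraries: it was 288 without control library 1, 274, 293, 351 and 1645 without cytochalasin D libraries 1 to 4, 251 and 366 without apoptotic libraries 3 and 4, and 275 and 266 without libraries 3 and 4 with both treatments. The negative differences numbered 125 without control library 4 and 334 without library 1 with both treatments, and the positive ones 245 without library 2 with both treatments, and without the 3 libraries that stood apart the count was 120. With DESeq2 it was 976 (642 positive, 334 negative), and without a filter on low counts 928.

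The genes that changed with apoptotic cells were shared between the conditions with and without cytochalasin D more than independent lists would share them. Of the genes higher with apoptotic cells, 224 were higher in both (44.1 expected for independent lists), and 172 were lower in both (33.2 expected; Fisher's exact test across genes, Benjamini-Hochberg adjusted p = 6.33e-104 and 8.6e-80 over 8 tests, genes not being independent replicates). Of the 224, 65 were near 0 without apoptotic cells, and 159 were left without genes under 0.5 CPM in control and cytochalasin D libraries, a choice made after seeing the data. Trib3, Atf4, Nupr1, Oasl, Rapgef4 and Abca1 were lower, and Arhgef17, Nr4a3, Sgk1, Slc2a1 and Thbs1 higher, in both. Genes higher without and lower with cytochalasin D numbered 6, and genes lower without and higher with it 33 (34.7 and 42.2 expected; Fisher's exact test, adjusted p = 2.24e-09 and 0.142). Across all genes the log2 changes had a Pearson correlation of 0.684 and a Spearman correlation of 0.12, and the Pearson value was 0.151 among 9152 genes with a mean of at least 10 CPM. The Spearman correlation was 0.229 and 0.0289 without cytochalasin D libraries 1 and 4, and 0.0341 and 0.205 without libraries 1 and 4 with both treatments.

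Slc12a2-deficient and wildtype phagocytes, both sorted while engulfing, were compared to find which genes differ between them. Genotype and line are the same split of these libraries, so an effect of Slc12a2 and a difference between the lines cannot be told apart. Matrix genes were lower in deficient cells, 16 of 20 lower and 3 higher (19 adjusted over the list alone; camera adjusted p = 4.68e-06, and adjusted p = 0.178 with an estimated correlation). The matrix protein Postn was 18.6-fold lower, at 30.4 ± 1.94 against 564 ± 53.1 CPM (log2 -4.22, SE 0.07, edgeR adjusted p = 7.14e-15), the proteoglycan Bgn 9.88-fold, the protease inhibitor Timp1 1.95-fold, fibronectin Fn1 1.91-fold and the collagen Col6a2 1.90-fold lower, with edgeR adjusted p from 2.87e-13 to 2.39e-07. Sgk1 was 3.597-fold lower at 24.6 ± 3.64 against 88.4 ± 17.4 CPM (log2 -1.85, SE 0.13, edgeR adjusted p = 1.24e-08), and Nppb was 16.5-fold lower at 2.24 ± 0.518 against 36.7 ± 2.79 CPM (log2 -4.04, SE 0.12, edgeR adjusted p = 7.76e-13). Higher in deficient cells were the cytokine signalling suppressor Socs5, 6.44-fold at 49.8 ± 1.63 against 7.78 ± 2.58 CPM (log2 2.69, SE 0.14, edgeR adjusted p = 8.02e-10), the orphan receptor Gprc5a, 4.42-fold at 109 ± 4.65 CPM (edgeR adjusted p = 1.13e-09), and Cd320, 6.35-fold (edgeR adjusted p = 8.53e-10).

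Of 13050 genes tested, 5545 differed between the genotypes, 2759 higher and 2786 lower in deficient cells. Changes of at least 2-fold were more often decreases, with 510 genes lower and 194 higher. Several genes were close to absent in deficient cells: Pcdh12, a protocadherin, stood at 0.0485 ± 0.0385 against 12.3 ± 0.948 CPM, Slc14a2, a urea transporter, at 0.281 ± 0.126 against 59.8 ± 5.74 CPM, the netrin receptor Unc5b at 0.181 ± 0.0602 against 33.1 ± 2.93 CPM, and Ly6e at 0.211 ± 0.0735 against 37.3 ± 2.47 CPM (edgeR adjusted p from 7.48e-15 to 7.76e-13). The sulfatase Sulf2, Tdgf1 and Unc5c were likewise lower, by log2 changes of -6.98, -5.70 and -4.51 (edgeR adjusted p from 3.09e-13 to 5.76e-12). Retsat (4.05-fold), Hoxc8 (3.82-fold), the phosphatase Ptprs (3.48-fold) and the decoy receptor Il13ra2 (3.25-fold) were higher, with edgeR adjusted p from 9.16e-11 to 6.55e-08.

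Of 25 genes of the unfolded protein and integrated stress responses, 14 were lower and 2 higher (17 adjusted over the list alone; camera adjusted p = 0.000184, and adjusted p = 0.279 with an estimated correlation). Chac1 was 3.37-fold, Ppp1r15a 3.02-fold and Atf5 2.39-fold lower (edgeR adjusted p from 6.07e-11 to 2.21e-09). Of 28 lysosomal genes, 18 were lower and 2 higher (20 adjusted over the list alone; camera adjusted p = 0.000497, and adjusted p = 0.279 with an estimated correlation). Gpnmb was 2.21-fold and Cd63 1.35-fold lower (edgeR adjusted p = 2.29e-10 and 2.94e-06). Of 29 immediate early genes, 13 were lower and 2 higher (15 adjusted over the list alone; camera adjusted p = 0.0286, and adjusted p = 0.614 with an estimated correlation). Jun was 2.67-fold, Dusp4 2.65-fold and Egr3 1.87-fold lower (edgeR adjusted p from 2.57e-10 to 1.01e-06). Of 14 TGF-beta and BMP targets, 7 were lower and 2 higher (11 adjusted over the list alone; camera adjusted p = 0.0319, and adjusted p = 0.614 with an estimated correlation). Id1 was 1.87-fold lower at 11.8 ± 1.11 CPM (edgeR adjusted p = 3.41e-07), while Id2 was higher, at 19.4 to 35.7 CPM in deficient against 10.3 to 17.6 CPM in wildtype libraries. No list passed the camera test with an estimated correlation in this comparison, the lowest adjusted p being 0.178 for the matrix list.

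Inflammatory genes went both ways in deficient cells, 9 of 20 higher and 7 lower (17 adjusted over the list alone; camera adjusted p = 0.705). The growth factor Csf1 was 2.47-fold higher at 257 ± 3.16 against 104 ± 11.7 CPM (log2 1.30, SE 0.06, edgeR adjusted p = 3.16e-10) and Cxcl1 2.34-fold higher (edgeR adjusted p = 1.1e-05), while Il11 was 15.0-fold lower at 0.49 ± 0.215 against 7.46 ± 0.414 CPM (edgeR adjusted p = 2.35e-10) and Ptgs2 2.15-fold lower (edgeR adjusted p = 1.36e-09). Of 17 genes that restrain inflammation, 3 were higher and 7 lower (10 adjusted over the list alone; camera adjusted p = 0.447). Anxa1 was 1.79-fold lower (edgeR adjusted p = 7.34e-07). Of 25 genes of apoptotic cell uptake, 7 were higher and 8 lower (15 adjusted over the list alone; camera adjusted p = 0.58). The receptors Megf10, Cd36 and Mertk were 4.23-, 3.22- and 1.76-fold lower and the integrin Itgb5 1.40-fold higher (edgeR adjusted p from 2.72e-08 to 2.18e-05). The receptors Axl and Tyro3 were higher as well. Axl stood at 1842 to 1978 CPM in deficient against 1674 to 1803 CPM in wildtype libraries. Tyro3 stood at 46.9 to 58.1 against 42.8 to 48.8 CPM, with overlapping groups. Mertk was far less abundant, at 5.36 to 6.46 CPM in wildtype libraries. Of 21 chloride sensing genes, 6 were higher and 5, with Slc12a2, lower (11 adjusted over the list alone; camera adjusted p = 0.655). Cab39l was 1.95-fold and Stk39 1.11-fold higher and Lrrc8c 1.42-fold lower (edgeR adjusted p = 2.51e-08, 0.0107 and 2.17e-06). Oxsr1 and Slc16a1 did not pass (log2 -0.03 and -0.09, edgeR adjusted p = 0.564 and 0.176), and Slc2a1 and Hk2 were 1.24- and 1.57-fold lower (edgeR adjusted p = 0.000353 and 2.75e-06). Of 183 solute carriers, 35 were higher and 50 lower (88 adjusted over the list alone; camera adjusted p = 0.54).

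**Figure D3:**
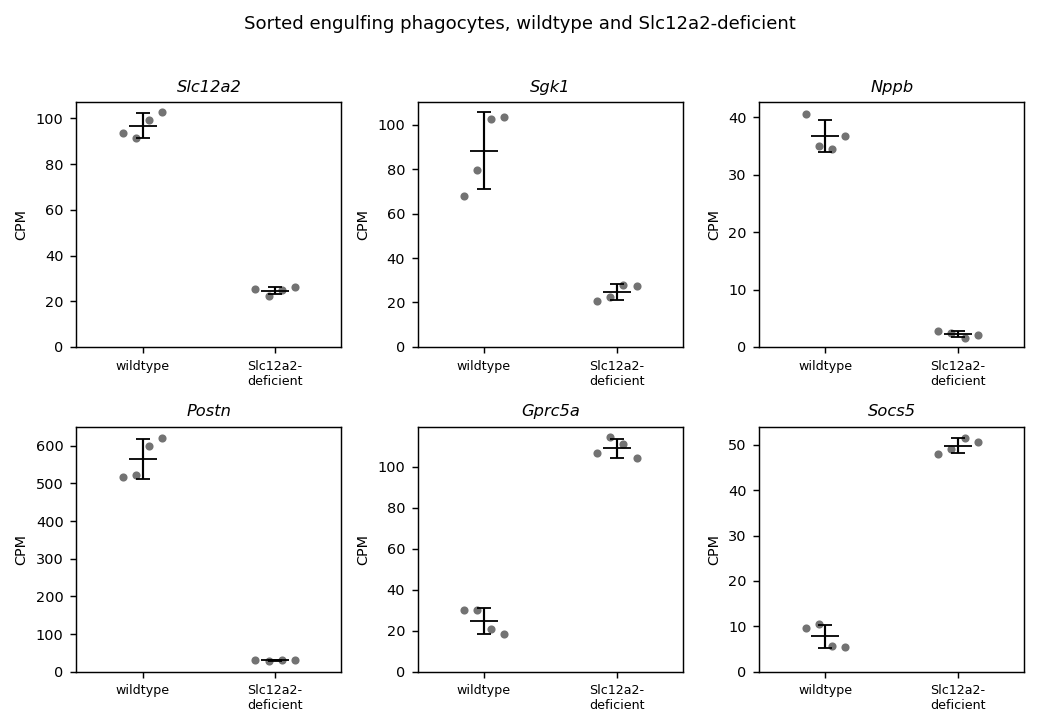
Expression in CPM (vertical axes) of Slc12a2, Sgk1, Nppb, Postn, Gprc5a and Socs5 in sorted wildtype and Slc12a2-deficient phagocytes (horizontal axes). Dots are single libraries and bars the mean ± SD of 4, with Slc12a2 at 96.8 and 24.7 CPM and Postn at 564 and 30.4 CPM.

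Genes that changed with apoptotic cells were then set against those that differed by genotype, among the 12569 genes tested in both experiments, which share no library. Genes lower in deficient cells and higher with apoptotic cells numbered 265 (172 expected for independent lists), and genes higher in deficient cells and lower with apoptotic cells 296 (190.0 expected; Fisher's exact test across genes, Benjamini-Hochberg adjusted p = 9.4e-15 and 1.75e-17 over 8 tests, genes not being independent replicates). Sgk1, Id1, Il11, Ptgs2 and Slc2a1 were among those higher with apoptotic cells and lower in deficient cells. Id2 and Arhgef17, also higher with apoptotic cells, were instead higher in deficient cells. The same direction was seen for fewer genes than expected, 118 higher in both and 147 lower in both (175 and 186 expected; Fisher's exact test, adjusted p = 1.91e-07 and 0.000806). Across genes the log2 changes had a Pearson correlation of -0.13 and a Spearman correlation of -0.115. The count of 265 was 175 without control library 1 and 165 without apoptotic library 3.

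**Figure D4:**
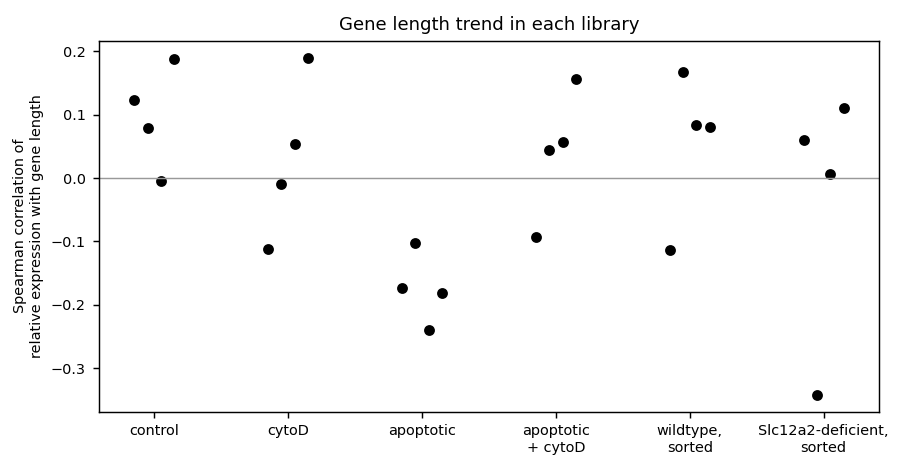
Spearman correlation between a gene's relative expression in a library (its log2 CPM minus the mean over the libraries of the experiment) and its length, on the vertical axis, for each of the 24 libraries, by group on the horizontal axis. The 4 apoptotic libraries lie between -0.239 and -0.103, the control libraries between -0.00515 and 0.188. The lowest value, -0.342, is that of Slc12a2-deficient library 2, and cytochalasin D library 1 lies at -0.112.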

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

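The share of near-0 genes in sorted cells and the level of neighbouring genes were tests chosen only after the results they measure were seen, and the length test was chosen after the trend was seen, with its bounds written before its result.

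Groups of 4 libraries were checked for the named genes and for depth, T cell share, share of the 20 most abundant genes and genes detected. Of these 351 groups, 17 (4.84%) held a library far from the other 3 by Dixon's criterion at 95%, where chance gives about 1 in 20. In the first experiment these were Bola1 at 24.82 CPM and Cdc20 at 326 CPM in apoptotic library 3, and Gem at 8.531, Mcm6 at 166.2 and Dusp5 at 66.07 CPM in cytochalasin D library 4. Amotl2 at 124.3 and Cxcl3 at 27.1 CPM stood apart in cytochalasin D library 1, and Zap70 at 5.104 CPM in library 1 with both treatments. In control libraries these were Sqstm1 at 71.08 CPM in library 2, Cyr61 at 55.67 CPM in library 3, and Ankrd1 at 1.351 CPM in library 4. In the second experiment they were Postn at 27.51, Chac1 at 6.45 and Lat at 5.721 CPM in deficient library 2, Ptprs at 139.7 CPM in deficient library 3, Hoxc8 at 3.415 CPM in wildtype library 2 and Dusp4 at 70.82 CPM in wildtype library 3.

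The effect of apoptotic cells differed with cytochalasin D for 23 named genes (edgeR, test of the difference itself, log2 effect with minus without). The difference was positive for Ankrd1 (1.77), Thbs1 (1.497), Ptprr (1.11), Nppb (1.003), Vgll3 (1.003), Cyr61 (1.001), Hbegf (0.979), Idi1 (0.931), Msmo1 (0.77), Hmgcs1 (0.53) and Oxsr1 (0.216). It was negative for Id1 (-1.92), Id3 (-1.55), Gli1 (-1.18), Egr3 (-1.09), Ccr7 (-1.08), Ddit4 (-1.08), Sgk1 (-1.02), Cxcl1 (-0.88), Cxcl3 (-0.832), Id2 (-0.808), Col6a1 (-0.529) and Col6a2 (-0.494).

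Of the 914 genes higher with apoptotic cells, 74 were near 0 without them, and 48 of these had no symbol. Of the 74, 71 (95.9%) lay under 0.5 CPM in the sorted wildtype phagocytes, where Lck and Zap70 were at 0.0585 and 0 CPM, and their gain with over without cytochalasin D had a median of 1.22 (interval 1.01 to 1.35), against 1.07 (0.887 to 1.54) for 5 of the 13 T cell genes measured that were near 0 without apoptotic cells. Human RNA of Jurkat cells counted on hamster genes is a candidate source of these 74, with Zap70, Lck and Lef1, the most abundant of the 5, at 3.35, 3.20 and 1.68 CPM. Whether the sort in the second experiment removed free corpses was not measured, and it selected cells marked for engulfed ones. For the 840 genes expressed without apoptotic cells the median was 0.19 (0.154 to 0.237). It argues against Jurkat RNA as the source for this set as a whole, but not for single genes. These genes were picked as higher with apoptotic cells alone, which by itself lowers this median by an amount not measured. The length trend in that comparison may lower it as well. For 94 of them at least 2-fold higher the median was 0.337 (0.143 to 0.642). Of those, 34 lay under 0.5 CPM in the sorted wildtype cells, so some of them stay open. A response of the phagocytes was not tested separately from these.

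In Slc12a2-deficient phagocytes 82 genes were at least 8-fold lower, and 71 of them were under 0.5 CPM, against 15 at least 8-fold higher. Loss of a single chromosome segment holding most of these genes was argued against by gene order. There, 14 of 69 placed genes (20.3%) lay within 5 places of another, under the bound of 25% written before. The 14 were above the 3.94 expected (permutation p = 0.0019 over 10000 sets), so loss of smaller segments holding some of them stays open. Of 127 genes next to them and not themselves at least 8-fold lower, 117 (92.1%) stayed above 50% of the wildtype level, with a median log2 change of -0.05. Neighbours at least 8-fold lower were left out of this share, so it cannot decide on segment loss. In the first experiment 19 of the 82 (23.2%) lay above 50% of the sorted wildtype level with apoptotic cells, and 14 in the control, so most were low there as well. The bound written for this test was wrong because either line may be the one that differs and the cells of the first experiment were not sorted, so a difference between the lines and the effect of Slc12a2 cannot be told apart, genotype and line being the same split.

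Fold changes with apoptotic cells fell with gene length (Spearman correlation across genes -0.256, and -0.0341 once each library's trend was removed), with median lengths of 1706 bases for higher and 3775 for lower genes. With the trend removed, 1395 of 1789 genes (78%) kept their call, between the bounds of 50% and 80% written before, and 1625 were called. The 394 lost had a median absolute log2 change of 0.214 before and 0.165 after, with a median SE of 0.0642 and 0.0628, so those calls ended because the change shrank. For the difference between effects, 456 of 598 (76.3%) kept their call, and the 142 lost went from 0.329 to 0.272 with an SE of 0.0884 and 0.0843. A length trend between libraries and a response to apoptotic cells that depends on gene length cannot be told apart for the lost genes, since the 4 apoptotic libraries all lie below the control ones in this trend.

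Counts for the 4 comparisons between groups were set against those from other splits of the libraries. Each other split mixes the compared groups, whose difference then enters the spread, so these splits cannot exclude chance as the source. Of 35 splits of 8 libraries, 1, the real one, gave as many genes as 1789 with apoptotic cells (highest other 0), 3451 with cytochalasin D (highest other 0), 1129 with apoptotic cells under cytochalasin D (highest other 699, with cytochalasin D library 4 beside libraries 2, 3 and 4 with both treatments) and 5545 by genotype (highest other 4). For the difference between effects, 1 of 100 regroupings gave 598 or more (highest other 12), but these regroupings mix the treatments, whose effects then enter the spread, so they do not show whether chance gives this count.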

How the results depend on the processing

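Settings that remove the length trend, 3 libraries apart on the third principal component or genes near 0, and single libraries left out of overlaps, correlations, the target level and the T cell share, were tests chosen only after seeing the data. Values below are genes changed (higher, lower). At an adjusted p under 0.01 counts were 785 (422, 363) with apoptotic cells, 2233 (1152, 1081) with cytochalasin D, 532 (321, 211) with apoptotic cells under cytochalasin D and 132 (86, 46) for the difference between effects, and with a minimum fold of 1.5 they were 79 (77, 2), 224 (156, 68), 87 (83, 4) and 4 (2, 2), and 825 (297, 528) by genotype, as stricter thresholds call fewer genes. For the difference, DESeq2 gave 976 (642, 334), and no filter 928, with 385 lower. Without the 3 libraries apart, the count under cytochalasin D was 662 (385, 277) and that of the difference 120 (75, 45). The Pearson correlation of the effects of apoptotic cells was 0.151 among genes of at least 10 CPM and 0.211 without genes near 0. The cause was not tested for these changes, except where the threshold or fewer libraries make it.

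With each library left out, counts ranged from 1103 to 1700 (537 to 845 higher, 566 to 855 lower) with apoptotic cells, lowest without apoptotic library 3, with 606 higher without control library 1. They ranged from 2866 to 3596 (1465 to 1767, 1401 to 1829) with cytochalasin D, from 756 to 1639 (440 to 914, 308 to 725) with apoptotic cells under cytochalasin D, from 251 to 1645 (166 to 909, 85 to 736) for the difference and from 4774 to 5690 (2359 to 2861, 2397 to 2829) by genotype. Shared genes ranged from 184 to 231 higher and 131 to 195 lower in both, from 165 to 305 lower in deficient and higher with apoptotic cells and from 200 to 334 the other way. The correlations ranged from 0.614 to 0.709 (Pearson) and 0.0289 to 0.229 (Spearman), and Slc12a2 from 25.1% to 26.3% of wildtype.

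Replicate numbers in the first experiment are not stated to pair libraries, and of 24 same-number pairs 3 had correlated deviations over 0.1 (median 0.00478), with 1 library closest to its own number. Between cytochalasin D alone and both treatments, libraries 1 gave 0.206 and libraries 4 gave 0.227. Library 1 of either group with library 4 of the other gave -0.267 and -0.222. Libraries 2 and 3 gave 0.00618 and 0.0236. A trend with library number within these groups thus stays open. With a replicate block the counts were 1863, 3412, 1117 and 753 in the order above, and with the library-number set as a block 6226 by genotype, where 5 of 8 set pairs were over 0.1. All 8 were positive (0.0367 to 0.141, median 0.108), while pairs from different sets had a median of -0.105. Libraries of the second experiment thus differed by set. Each set held both genotypes, and the main fit left the set out, so its spread includes that difference. The replicate block ended the list call of immediate early genes for apoptotic cells under cytochalasin D (camera adjusted p = 0.0518), passed Slc12a2 (0.0485) and Slc16a1 (0.0336) for the difference, and changed no other named call.

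Tallies for single named genes exclude Cebpd, Nr4a3 and Il11 calls dropped because single libraries ended them, so they understate such losses. Of the rest, 4085 alternative values kept direction and side of the threshold, 118 lost the call, 11 gained it and 11 changed sign, the last among genes without a call. Signs changed under cytochalasin D for Oxsr1 (-0.0231 without cytochalasin D library 1, -0.00349 without 3, -0.00684 and -0.0134 without libraries 3 and 4 with both treatments, -0.0456 without the 3 apart; range with single libraries out up to 0.0465) and Stk39 (-0.0108 and -0.0137 without cytochalasin D libraries 2 and 3, -0.0116 and -0.00946 without libraries 1 and 3 with both treatments; up to 0.0368), and with apoptotic cells for Slc16a1 (0.0157 without apoptotic library 3, down to -0.0499 without apoptotic library 4, 0.00843 with the length trend removed). The cause was not tested. The minimum fold of 1.5 accounts for 87 lost calls. Without the 3 libraries apart, calls were lost by Slc12a2 and Oxsr1, whose log2 changes shrank from 0.33 to 0.18 under cytochalasin D and from 0.22 to 0.14 for the difference (edgeR adjusted p = 0.302 and 0.309). Calls were also lost by Slc16a1 under cytochalasin D at 0.16, and by Egr3 and Cxcl1 for the difference at -0.90 and -0.76 (edgeR adjusted p = 0.0691, 0.0954 and 0.0795), each at over 80% of its size with all libraries. Among lists, 366 values kept their side, 29 lost the call, 25 of them with an estimated correlation, and 42 gained it, 39 of them with fry, which tests a list against no change and not against other genes. With the length trend removed the Nrf2 and p53 lists passed with apoptotic cells (camera adjusted p = 0.0291 and 0.03), LXR for the difference (0.0142), and immediate early genes for apoptotic cells under cytochalasin D did not (0.0508). Depth limits genes near the floor of 3 counts, 0.105 to 0.363 CPM per library.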

Other observations

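No test reported in this part was chosen after its result was seen. Of 27 oxidative stress and Nrf2 genes, 5 fell and 1 rose with apoptotic cells under cytochalasin D (7 adjusted over the list alone; camera adjusted p = 0.000137, and adjusted p = 0.00604 with an estimated correlation), and Nfe2l2, the Nrf2 gene itself, was 1.23-fold lower (edgeR adjusted p = 3.42e-05). Without cytochalasin D 3 rose and 5 fell (9 adjusted over the list alone; camera adjusted p = 0.17). Of 18 hypoxia genes, 2 rose and 1 fell with apoptotic cells (4 adjusted over the list alone; camera adjusted p = 0.363), and with cytochalasin D 6 rose and 2 fell (10 adjusted over the list alone; camera adjusted p = 0.291). Of 27 uptake genes, 12 rose and 3 fell with cytochalasin D (17 adjusted over the list alone; camera adjusted p = 0.119). Of 17 p53 targets, 4 fell with apoptotic cells under cytochalasin D (5 adjusted over the list alone; camera adjusted p = 0.00414, and adjusted p = 0.026 with an estimated correlation).

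Of 20 myeloid markers 3 were measured, and Cd68 and Lgals3, which fibroblasts also express, made up the 2 that rose with cytochalasin D (2 adjusted over the list alone; camera adjusted p = 0.154) and the 2 lower in deficient cells (2 adjusted over the list alone; camera adjusted p = 0.334). The list took 156 ± 15.3 ppm of counts with cytochalasin D and 131 ± 3.87 in the control, 144 ± 4.12 with apoptotic cells against that control, 121 ± 10.7 with both treatments against cytochalasin D alone, and 42.8 ± 9.25 in deficient against 76.7 ± 9.16 in wildtype cells (exact permutation p = 0.0286 for each, Benjamini-Hochberg adjusted p = 0.0763 over 32 tests, 4 of 4 libraries each). Of 13 mitochondrial RNA names 1 was measured, COX1 over 69 bases, and it fell with apoptotic cells (1 adjusted over the list alone), at 0.00895% ± 0.00107 against 0.0109% ± 0.00159 of counts (exact permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.0763).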
